A study of Oryza sativa with 2 samples.

How the data were processed

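Chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound by a protein is pulled down with an antibody and sequenced, was applied to rice shoots. Per the labels, the plants carried a transgene that expresses the rice transcription factor OsWRKY11 fused to a Myc tag from a ubiquitin promoter, and 2 g of shoots were fixed in 1% formaldehyde. The series has 2 samples: 1 library pulled down with an anti-Myc antibody and 1 input, that is, DNA of the same kind of material sequenced without an antibody. There was no replicate of either, and no library from plants without the tag was analysed here. The sample titles carry the tag 30D, whereas the design text gives an age of 3 weeks, and the difference was left open.

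The submitters' processing notes name Trimmomatic 0.36, BWA 0.7.12-r1039 and MACS2 2.2.7.1. The settings, the genome build and the treatment of duplicate reads are not given in the sources used here. The authors deposited 1 list of peaks called from the ChIP library against the input, per the peak names in the file. Per the file headers, each peak has a pileup, which is the signal (coverage by ChIP fragments) at its summit. Per the file headers, the list also gives the fold enrichment of the ChIP signal over the background, a ratio. The p-value and q-value of each peak were deposited as −log10 values, per the file headers. The fold, p and q printed here are the authors' own values for each peak. Start positions are 1-based, since the deposited length equals the end minus the start plus 1. The sequences are named Chr1 to Chr12, ChrUn and ChrSy, and positions are given in those coordinates.

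The rest was computed from the list with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The background at each summit, the number of ChIP fragments expected without binding, was solved from the pileup and the fold as (pileup + 1)/fold − 1. With these backgrounds the upper tail of a Poisson distribution gave back every deposited −log10 p-value to within 0.000336. The most common background, 5.69 fragments, was taken as the genome-wide floor, and 3867 of 6672 peaks lay within 0.001 of it. A background above the floor reflects locally higher input coverage. Among the 1014 backgrounds over 1.15 times the floor, 828 (81.7%) were whole multiples of 0.410 to within 0.05 fragments, where 10% would be so by chance. At other spacings, away from this one and its nearest multiples, the highest share was 51.9%. That share was counted without the highest backgrounds, and some of those spacings may be related to 0.410. The spacing of 0.410 was read as the weight of 1 input fragment after scaling, so that the input held 2.44 fragments for each ChIP fragment. Total reads per library are not given in the sources used here, and this ratio and the floor are the depth information used. All pileups were whole numbers.

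Peaks were described at q of 0.05 or below, at a fold of at least 4, and by whether the background was at least 2 times the floor (called high-background). Fold intervals are 95% intervals from the exact Poisson limits of the ChIP pileup with the background held fixed. For high-background peaks with a whole number of input fragments, the scaled ratio of ChIP to input fragments was given with exact Clopper-Pearson limits, which include the counting error of the input. Shares have 95% Wilson intervals. All intervals cover counting error only, since copies made by PCR are not independent fragments. Unequal shares over the 12 chromosomes were tested with a permutation test (100000 resamples, upper tail of a chi-square statistic), and each chromosome against the rest with Fisher's exact test (two-sided). Peaks past q with another such peak within 20 kb were counted and compared with 1000 draws of the same number of peaks per sequence from the whole list (one-sided). Regions are runs of at least 4 such peaks with gaps of at most 20 kb. Ratios within a region of high background were compared with a permutation of fragments between libraries, with p-values adjusted over the regions tested. A chance undercount of the input was tested with the binomial tail at a ratio of 1, multiplied by the bases up to the last listed position of each sequence. Peaks and fragments are not biological replicates, so each p describes these 2 libraries and not plants. The chromosome tests count each peak as independent, so their p-values may be too small where peaks lie close together. On simulated data built on the same 6672 peaks, the floor and the spacing were recovered. With as many peaks flagged as passed q (1053), the chromosome test gave p under 0.05 in 4.5% of 200 draws without an effect. It did so in 100% of 100 draws with 1 chromosome doubled, and the neighbour test in 2.5% of 40 draws without an effect. All these draws flagged peaks without regard to their neighbours. For draws without an effect this is what the tests assume, so a rate near 5% was fixed in advance and checks only the code. Calibration for peaks that lie close together was not checked. No such simulation was run for the 42 peaks with a fold of at least 4. The power of the chromosome test for those is therefore not known.

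The count of peaks and its 4 alternatives (2 stricter q limits, merging within 500 bp, and a fold of at least 4) were fixed before the data were examined. The share of summits in promoters, W-boxes and 6-mers near summits, the fold of peaks with and without a W-box, and gene lists had also been planned. They are not analysed here, because no sequence or annotation of the genome behind these coordinates was used. The gene table at hand belongs to another assembly, so no peak was assigned to a gene. The naming rule, fixed in advance, was to name fixed genes and list members by their strongest peak and the 10 peaks of highest fold near a described gene. Only its last part could be followed, for positions instead of genes. The background, the regions, the neighbour counts and the comparison of chromosomes were chosen after the list was seen.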

Results

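OsWRKY11 belongs to the WRKY family of plant transcription factors, which bind DNA through a WRKY domain. The series concerns how the amount of this factor bears on heading, the emergence of the rice panicle, and its ChIP-seq experiment asks where in the genome the tagged factor sits in shoots. The data were 1 anti-Myc ChIP library and 1 input library from shoots of the OsWRKY11-Myc line, deposited as a list of 6672 peaks. The design implies 1 comparison, ChIP against input, without replicates. Positions are given in the coordinates of the deposited list and were not assigned to genes.

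The ChIP of the tagged factor gave few strong sites and many weak ones. Of the 6672 peaks, 6660 lay on the 12 numbered chromosomes, 9 on ChrSy and 3 on ChrUn. The median fold enrichment over background was 2.39, with quartiles of 2.23 and 2.54, and the highest was 19.7. A fold of at least 3 was reached by 299 peaks (4.48%), of at least 4 by 42 peaks (0.63%) and of at least 5 by 15 peaks (0.225%). The peaks were narrow, with a median width of 231 bp and a range from 180 to 2224 bp.

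Most peaks did not pass a false discovery rate of 5% by the authors' own q-values. The q-value was at or below 0.05 for 1053 peaks (15.8%) and above it for 5619 (84.2%), and 1074 peaks (16.1%) had a q of at least 0.5. The median q was 0.278 and the highest 0.737. A q of 0.01 or below was reached by 604 peaks, a −log10 q of at least 5 by 167 and of at least 10 by 94. No fold lay below 2.00 and no pileup below 13. At the floor background of 5.69 fragments, a pileup of 12 would have had a fold of 1.94. Peaks past q had a median pileup of 19 fragments and a median fold of 2.84, against 15 fragments and 2.26 for the others.

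**Figure D1:**
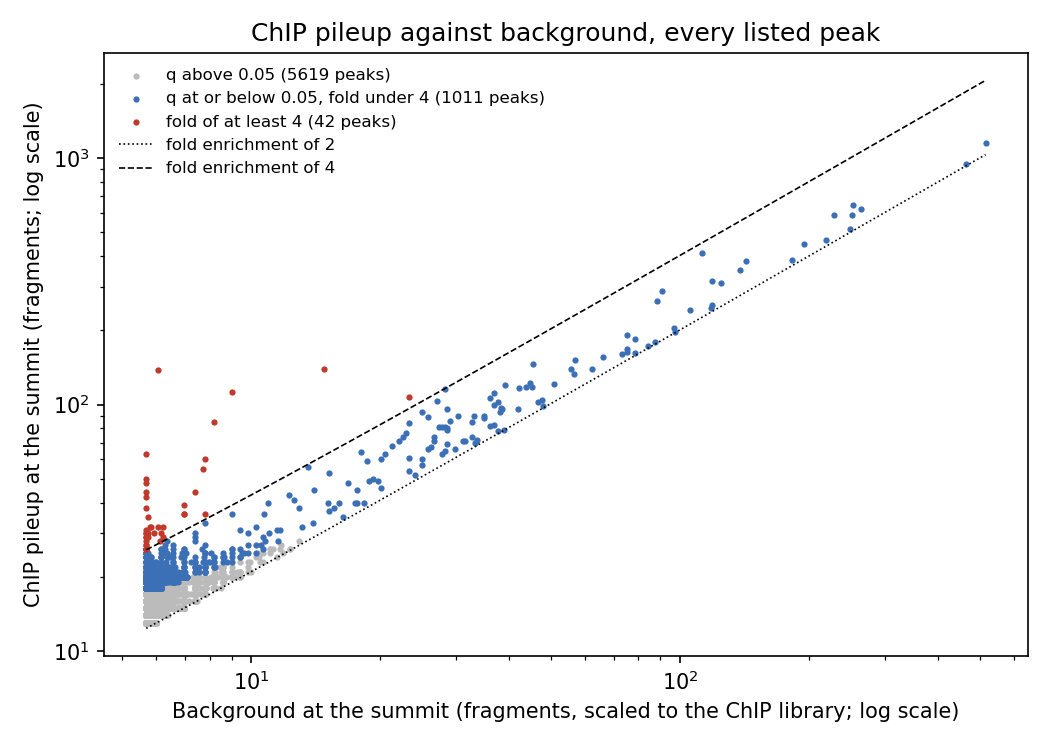
Pileup of ChIP fragments at the summit of each of the 6672 peaks (vertical, log scale) against the background solved from the deposited fold (horizontal, log scale), with dotted and dashed lines at folds of 2 and 4. The 42 peaks with a fold of at least 4 sit mostly near the floor of 5.69 fragments. The peaks over high backgrounds lie above the line of fold 2, as all listed peaks do, with a median fold of 2.47 and a highest of 8.95.

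The strongest site in the list lay on chromosome 6 at 4982779 to 4983019. Its summit at 4982817 carried 138 ChIP fragments over a background of 6.05, a fold of 19.7 (95% interval 16.6 to 23.3). The second lay on chromosome 3 at 5944468 to 5944735, with 113 fragments and a fold of 11.4 (9.40 to 13.7). A site on chromosome 2 at 33285969 to 33286279 had 63 fragments and a fold of 9.57 (7.39 to 12.2) over the floor background. On chromosome 9 the site at 18138883 to 18139156 had 85 fragments and a fold of 9.35 (7.49 to 11.5). The intervals of the 3 sites after the strongest overlapped, so their order is not resolved at this depth.

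The remaining 6 of the 10 highest folds lay between 6.43 and 8.95. The site on chromosome 5 at 11896261 to 11896441 had 140 fragments and a fold of 8.95 (7.54 to 10.6), and it was the only one of the 10 over a high background, 2.59 times the floor. That background rests on 36 input fragments, and with their counting error the scaled ratio was 9.49 (6.54 to 14.1). Its width of 181 bp was 1 bp above the smallest in the list, 180 bp. Chromosome 8 held a site at 27198611 to 27198843 with a fold of 7.63 (5.70 to 10.01) and one at 16240803 to 16241037 with a fold of 7.33 (5.44 to 9.67). The site on chromosome 4 at 31360580 to 31360805 had a fold of 6.94 (5.33 to 8.91). The site on chromosome 7 at 3989475 to 3989764 had a fold of 6.73 (4.93 to 8.98), and that on chromosome 3 at 6226870 to 6227255 a fold of 6.43 (4.68 to 8.64). Another peak on chromosome 3, at 6259723 to 6259942, had a fold of 4.64 (3.18 to 6.55).

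Peaks over high input coverage were set apart by a limit on the background chosen after the list was seen, and no gap at that limit was tested. The background was at the floor for 3867 peaks (58.0%) and above it for 2805 (42.0%), and at 134 peaks it was at least 2 times the floor. These high-background peaks had a median fold of 2.47, from 2.00 to 8.95, and 127 of them passed q, which is 12.1% of all peaks that did. They made up 76 of the 94 peaks with a −log10 q of at least 10. At folds under 2.5, 66 of 73 high-background peaks passed q, against 15 of 4280 of the others (q depends on the number of fragments as well as on the fold). Without the high-background peaks, 926 peaks passed q.

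The highest background in the list lay on chromosome 9 at 1075 to 3298, the widest peak, with 1147 ChIP and 1259 input fragments at its summit. Its background was 90.7 times the floor and its fold 2.22 (2.09 to 2.35). On chromosome 6, the peak at 15483043 to 15483233 had 948 ChIP and 1132 input fragments and a fold of 2.04 (1.91 to 2.18). On chromosome 2, adjacent peaks at 28719689 to 28721006 and 28721333 to 28721957 had folds of 2.54 (2.35 to 2.75) and 3.66 (3.32 to 4.03), with intervals that did not overlap. With the counting error of the input, their scaled ratios were 2.55 (2.28 to 2.85) and 3.69 (3.16 to 4.31). In the same way the peak on chromosome 9 had a ratio of 2.22 (2.05 to 2.41) and that on chromosome 6 one of 2.04 (1.87 to 2.23).

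Peaks past q lay closer together than draws from the same list. Another such peak lay within 20 kb for 251 of 1053 (23.8%), against a mean of 141 and a highest value of 188 in 1000 random draws. The p of 0.001 was the smallest the draws can give. Without the high-background peaks the count was 158 of 926 against a mean of 107 in the same permutation of peaks (p = 0.001). In all, 88 peaks formed 13 regions of at least 4 linked peaks, 8 of them with a median background of at least 2 times the floor and 5 with a lower one.

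Among the regions with high background, chromosome 11 held 16 peaks between 12078951 and 12123478, with folds of 2.00 to 3.42, flanked by 4 peaks between 12039875 and 12043790 and 7 between 12151162 and 12177990. On chromosome 5, 15 peaks past q between 29885179 and 29957417, the last listed position of that sequence, had folds of 2.04 to 4.43 and a median background 5.04 times the floor. Chromosome 6 had 4 peaks between 15467323 and 15484034, with a median background 45.4 times the floor, and 6 peaks between 66889 and 86668. The others lay on chromosome 12 between 5614220 and 5658080 and on chromosome 2 between 13703360 and 13716843, with 4 peaks each.

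The 5 regions with low background held 28 peaks past q. Chromosome 10 had 8 peaks between 5104963 and 5134651, with a median fold of 3.17 and a highest of 3.74, and 5 peaks between 3209191 and 3231295. Chromosome 3 had 4 peaks between 13362416 and 13366271 and 5 between 13468538 and 13479199, the latter with a highest fold of 4.85. Chromosome 2 had 6 between 21246079 and 21298108, with a highest fold of 3.44.

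**Figure D2:**
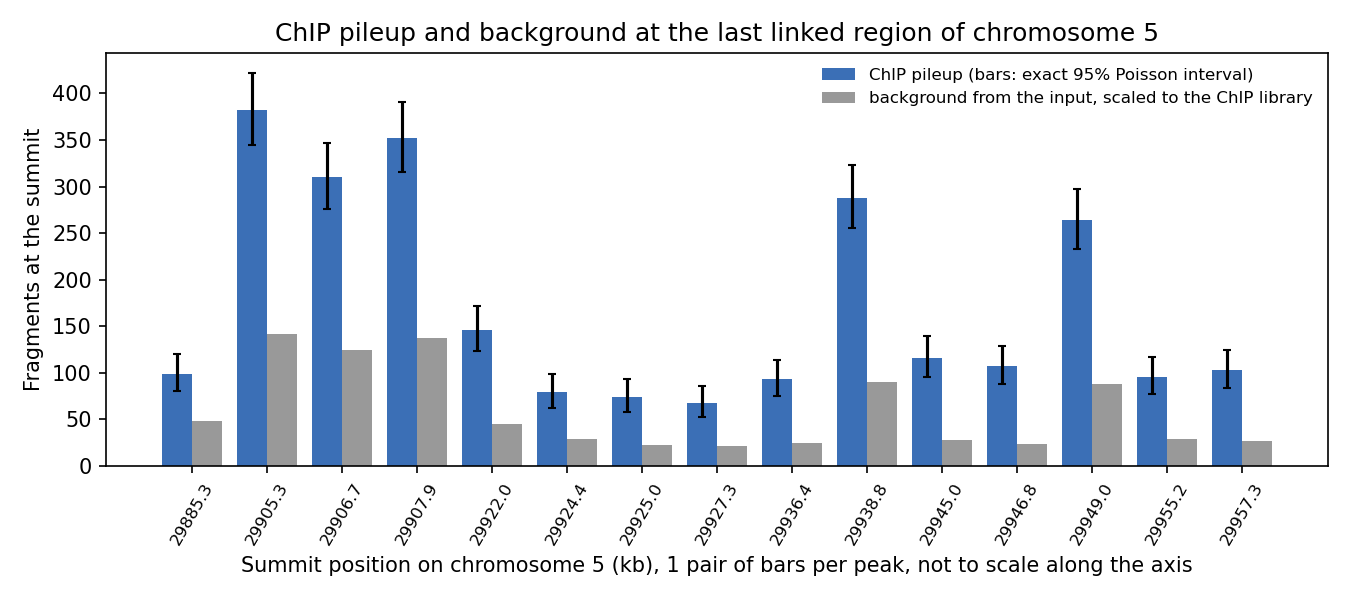
ChIP pileup (blue) and scaled background from the input (grey), in fragments at the summit, for the 15 peaks past q between 29885179 and 29957417 on chromosome 5, with summit positions in kb on the horizontal axis and exact 95% Poisson intervals on the ChIP bars. The folds run from 2.04 to 4.43. No listed peak has a fold below 2.00, so ChIP bars above the background follow from the listing.

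The chromosomes did not differ detectably in the share of peaks that passed q. It ranged from 13.1% on chromosome 9 (50 of 381, 95% interval 10.1 to 16.9%) to 19.2% on chromosome 5 (109 of 569, 16.1 to 22.6%), with p = 0.198 in a permutation test and 0.198 after adjustment over 2 tests. Of the 42 peaks with a fold of at least 4, 11 lay on chromosome 3 (1.66% of its 664 peaks, 0.928 to 2.94%) and 1 on chromosome 1 (0.119% of 843, 0.0209 to 0.669%). No other chromosome had more than 5. Over the 12 chromosomes these shares did not pass the permutation test (p = 0.0928, adjusted 0.186). The power of this test with 42 peaks was not simulated, so a difference may have been missed. For chromosome 3 against the rest, Fisher's exact test gave p = 0.00213, adjusted 0.051 over 24 tests that include the shares past q and 0.0255 over the 12 tests of this fold, so the call depends on the set of tests. At a fold of at least 3, a limit chosen after the data were seen, the chromosomes differed (permutation p = 0.0013, each peak counted as independent).

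**Figure D3:**
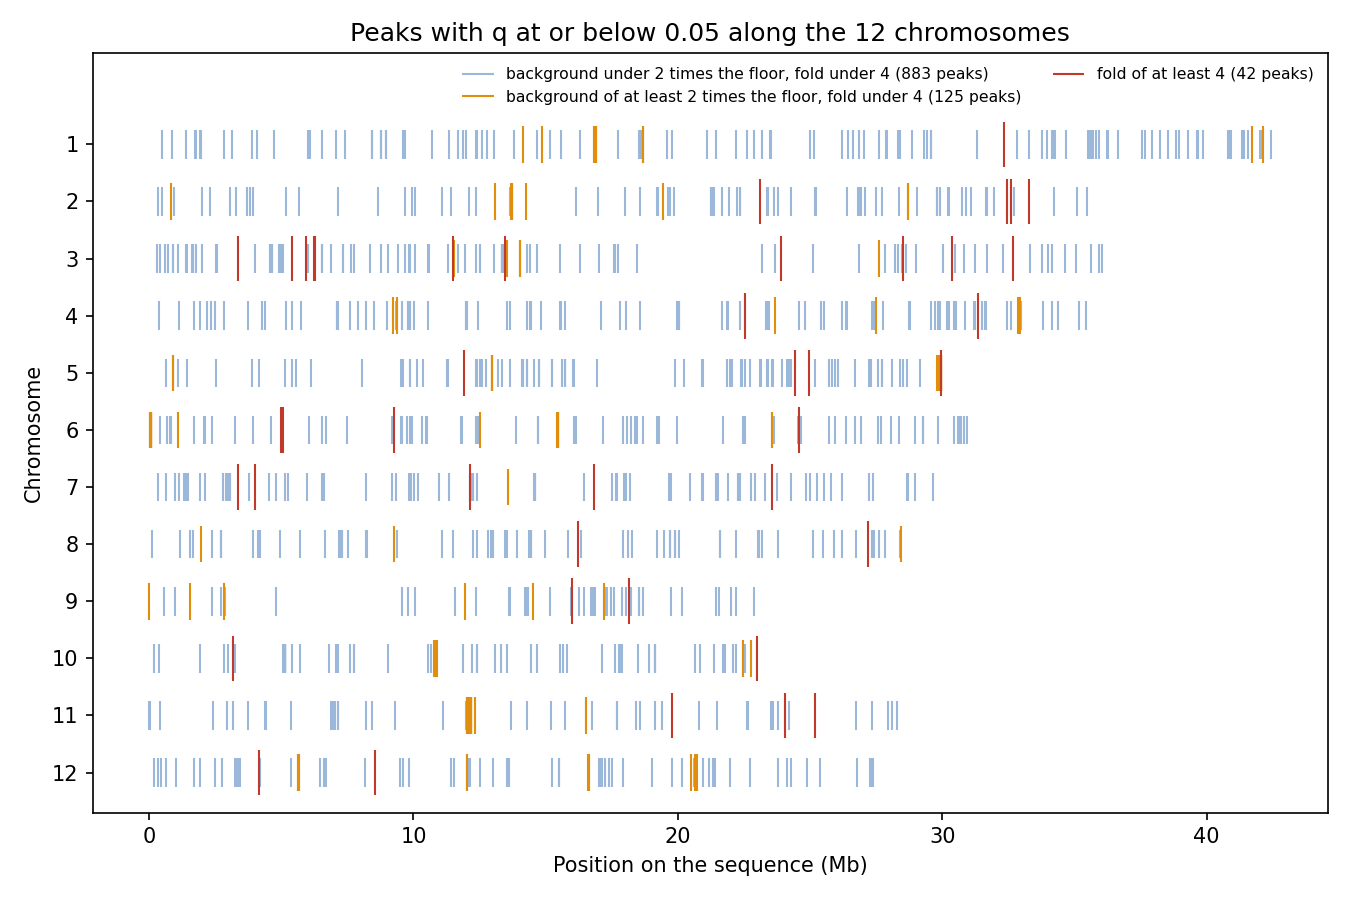
Positions in Mb of the peaks with q at or below 0.05 on the 12 numbered chromosomes, coloured by background and fold. The 42 peaks with a fold of at least 4 (red, tall) are spread over all 12 chromosomes with 11 on chromosome 3. Of the 127 high-background peaks past q (orange where the fold is under 4), 56 lie in linked regions such as those on chromosomes 5, 6 and 11. The others lie outside such regions.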

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

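Of 34 alternatives planned, 4 were run, all on the count of peaks, and the other 30 needed a genome sequence or gene positions and were not run; all other alternatives were chosen after the data were seen. The count of 6672 peaks depended on the limit: it was 1053 at q of 0.05 or below, 167 and 94 at −log10 q of at least 5 and 10, and 42 at a fold of at least 4. The 1053 peaks past q became 1657 at a q of 0.1 and 604 at 0.01. The 42 peaks with a fold of at least 4 became 78 when pileup was divided by background with no added fragment, and 242 peaks had a lower 95% limit of the fold of at least 2. The 13 regions became 5 without the high-background peaks, because fewer peaks entered. The unequal shares of strong peaks over chromosomes passed the test at a fold of at least 3 (permutation p = 0.0013) but not at 4 or 5. Far fewer peaks reach those folds (42 and 15, against 299), and the cause was not tested. The unequal ratios in the region at the end of chromosome 5 (permutation p = 0.0012) no longer passed with the counting variance doubled (p = 0.215); whether duplicates were removed is not given. The 56 high-background peaks beyond a chance undercount of the input became 22 with fragments counted in pairs. The adjusted p of chromosome 3 at a fold of at least 4 (Fisher's exact test) went from 0.051 over 24 tests to 0.0255 over the 12 of this fold. The remaining alternatives kept the direction and the side of the threshold, including the neighbour ratio of 1.77, which ranged from 1.30 to 28.9 over its 7 alternatives. With 1 library per group no replicate could be left out, and with the background held fixed the 63 ChIP fragments of a site such as that on chromosome 2 at 33285969 to 33286279 leave its fold an interval of 7.39 to 12.2.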

Other observations

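The tests in this part were chosen after the data were seen, except that the first input undercount test, on the lower limit of the ratio, had its prediction written before its result. In this list, a larger share of the peaks on chromosome 3 than elsewhere had a fold of at least 3. These include its 11 peaks with a fold of at least 4, so they are not separate support for an excess there. The limit of 3 was chosen after the data were seen, and the adjustments below do not cover that choice. At a fold of at least 5 the chromosomes did not differ detectably (permutation p = 0.634). Only 15 peaks reach that fold and the power with so few was not simulated, so this result does not speak against an excess. A fold of at least 3 was reached by 48 of its 664 peaks (7.23%, 95% Wilson interval 5.50 to 9.45%), against 250 of 5996 peaks (4.17%) on the other 11 chromosomes, with an adjusted p of 0.00842 over 12 Fisher's exact tests (0.0252 over 36, with those at a fold of 4 and of the share past q). Without the high-background peaks and the linked regions the shares were 43 of 650 (6.62%) and 218 of 5844 (3.73%), with an adjusted p of 0.0118. Chromosome 5 had 38 of 569 (6.68%, adjusted p = 0.0643 by Fisher's exact test), and 26 of 545 (4.77%) without the high-background peaks. No biological explanation was tested.

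Peaks over high input coverage had unequal folds within one region if fragments are independent. With the counting error of both libraries included, 0 of 108 such peaks had a lower 95% limit of the ChIP to input ratio at or below 1. The selection fixed this outcome, since the weakest peak it admits, with 24 ChIP and 28 input fragments, already has a lower limit of 1.16, so the prediction written for this test was wrong and it decides nothing. A test that allows for a search over all 373703323 bases up to the last listed positions, with fragments counted in pairs in case of duplicates, leaves chance no fold of 2 at 389 or more input fragments. There were 10 such peaks (largest binomial p times the bases, 2.35e-05). Every listed peak with so much input passes by construction, so the result is only that such peaks exist. If fragments occur at most in pairs, this argues against a chance undercount at these 10. More copies per fragment were not tried. Of the 98 peaks with fewer input fragments, 12 were beyond chance in the same test (46 with fragments counted singly), and a chance undercount stays open for the other 86. A block of sequence present in several copies but once in the reference would raise both libraries by the same factor. Copying alone would thus leave the ratio of ChIP to input unchanged, so one ratio per region is not by itself a test of copying. The peaks were also listed by fold, and the lowest ratio among the 108 was 2.03. Stretches with lower ratios were not seen, which makes the ratios within a region look more alike. Of the 8 high-background regions, 6 had at least 4 high-background peaks with a whole input count and were tested for one ratio per region, on those peaks only (12 of 16 and 5 of 7 on chromosome 11, 5 of 6 on chromosome 6, and all peaks in the other 3). The regions on chromosome 11 at 12039875 to 12043790 and on chromosome 12 at 5614220 to 5658080 were not tested. The ratios of the 15 peaks at the end of chromosome 5 ran from 2.07 (1.56 to 2.72) to 4.58 (3.29 to 6.43) and differed by more than the counting error of independent fragments (adjusted permutation p = 0.0072 over 6 regions). The treatment of duplicates is unknown, and with the counting variance doubled, a factor chosen after this p was seen, the unadjusted p rose from 0.0012 to 0.215, and a factor of 1.51 would bring it to 0.05. In the other 5 tested regions the smallest adjusted p was 0.0519. One ratio per region therefore stays open in all of them. A mapping artefact of repeats, open chromatin that any antibody recovers, and binding of the tagged factor stay open as well, untested.

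The 40 peaks with a fold of at least 4 over a low background had a median width of 279 bp, against 230 bp for the other low-background peaks (permutation p = 0.00365), and 1 of the 40 was under 200 bp wide, against 25.3% of the others. Stacked copies of single fragments would give widths near the smallest of 180 bp, a prediction written after the data were seen. The median of 279 bp lies above that. The fragment length is not given, however, and width rose with pileup among the others too (rank correlation 0.119). Over all low-background peaks the median width was 223 bp at 13 to 14 fragments and 231 bp at 15 to 19. It was 265 bp at 20 to 29 and 267 bp at 30 or more. The difference from 230 bp is thus not separate from pileup, so the widths do not decide, and stacked copies stay open. The summit lay within 25 bp of an end for 9 of the 40 (22.5%), against 749 of 6498 others (11.5%), as a steep drop on one side would give. Fisher's exact test gave p = 0.0433 there, the only one under 0.05 among 6 limits from 15 to 50 bp (0.0433 to 0.488, not adjusted). By pileup, the share within 25 bp was 10 of 36 low-background peaks at 30 fragments or more, 17 of 433 at 20 to 29, 250 of 3903 at 15 to 19 and 481 of 2166 at 13 to 14. The site on chromosome 5 at 11896261 to 11896441, a high-background peak outside this set, had a width of 181 bp with 140 fragments. Which of these sites depend on the tag remains untested.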
